A study of Mus musculus with 2 samples.

How the data were processed

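Single-cell RNA sequencing was carried out on CD45+ immune cells that had infiltrated subcutaneous B16F10 tumours, a transplantable mouse melanoma line, in Kcnj2f/f mice (WT) and Lyz2-Cre Kcnj2f/f mice (KO). Per the labels, tumours were taken at day 10, tumours of 3 mice were pooled for each library, CD45+ cells were sorted by FACS, and 6000 to 8000 cells were targeted with the 10x Chromium 3' v3 kit at about 48000 reads per cell. There was 1 library per genotype and therefore no replication of libraries.

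The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode, for 55450 genes, with no normalization. The submitters' processing notes name bcl2fastq 2.20, Cell Ranger 3.1.0, Seurat 4.0.1 and the mouse genome build GRCm38, whereas the header of the matrices names Cell Ranger 4.0.0; the version that made the matrices was left open. The smallest barcode total was 500 UMIs, so barcodes below that number were not in the matrices, and how they were removed is not given in the sources used here. All 55450 gene identifiers (100.0%) were found in GENCODE M21, from which coordinates were taken.

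Cells with at least 200 detected genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet as run by scanpy 1.11.5 (expected rate 0.06). Its own threshold marked 0 of 8936 WT cells and 2 of 5688 KO cells, far below the expected rate, so the caller did not work as a doublet filter here; the 2 marked cells were removed, and an alternative removed the 6% of cells with the highest scores in each library. Counts were scaled to 10000 UMIs per cell and logged, 2000 variable genes were chosen with the library as batch key, and cells were clustered on 30 principal components with 15 exact nearest neighbours and the Leiden method at resolution 1.0, without batch integration and with a fixed seed.

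Clusters were named from fixed marker lists for macrophages, monocytes, neutrophils, conventional type 1, conventional type 2, migratory and plasmacytoid dendritic cells, T cell subsets, NK cells, type 2 innate lymphoid cells, B cells, plasma cells, mast cells or basophils, melanoma cells, fibroblasts, endothelial cells, keratinocytes and erythroid cells. A cluster took the name of the highest-scoring list with at least 3 markers that were detected in at least 10% of its cells and lay more than 2 times above the other cells. A cluster stayed unnamed when its mean Scrublet score was at least 0.15, when cell cycle genes led it, when more markers of another class than of its own stood among its 10 leading genes, or when its cells had few UMIs and none of its class's markers stood among those 10. The marker lists were fixed in advance, but these limits were set after the clusters had been seen. Names are therefore written with the suffix -like. Unnamed clusters held 1949 WT cells (21.8%) and 667 KO cells (11.7%), of which a cluster led by cell cycle genes held 391 and 194. They were kept in the immune denominator but belonged to no class. Proliferation values of a class thus leave out the cluster led by cell cycle genes.

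Shares of each class among immune cells carry exact (Clopper-Pearson) binomial 95% intervals. For expression, raw UMIs were summed over the cells of a class in each library and scaled by the class total to the usual CPM. CPM values carry exact Poisson 95% intervals, and log2 ratios of KO over WT CPM carry exact conditional binomial 95% intervals. Where a library had 0 counts, 3 counts were taken as the floor. All intervals cover counting error only, since mice and libraries were not replicated, and no p-values, standard errors or numbers of changed genes were computed from cells. Classes among the macrophage, monocyte, neutrophil, dendritic, T and NK cells entered the expression comparison when each library held at least 200 of their cells.

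The named genes followed a fixed rule. Among genes with a mean CPM of at least 50 over both libraries, the 12 highest and 12 lowest log2 ratios were taken in macrophage-like cells and the 6 highest and 6 lowest in each other class, together with Kcnj2, Lyz2 and the members of the gene lists with the largest ratios. Xist, Y-linked, haemoglobin, immunoglobulin, T cell receptor, mitochondrially encoded and ribosomal protein genes and gene models without a proper symbol were left out of that ranking. The gene lists covered inflammatory (classically M1) and alternative (classically M2) macrophage genes, type I interferon and interferon-gamma responses, MHC class II and class I, chemokines, glycolysis, oxidative phosphorylation, the TCA cycle, glutamine and amino acid use, hypoxia, lysosome and phagocytosis, lipid handling, potassium channels, cytotoxicity, T cell inhibitory receptors, naive and memory T cell genes, proliferation, immediate early genes, neutrophil granule genes, mitochondrially encoded genes and sex-linked genes. List members with at least 20 UMIs over both libraries were used. A member was counted as higher or lower when its log2 ratio lay beyond 0.5 and its counting interval excluded 0. Each list median was ranked among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean expression, and its counting interval came from 1000 Poisson draws. Such a percentile describes these libraries only.

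The comparisons, filters, lists and the rule for named genes were fixed before the data were examined. The steps from counts to ratios and list percentiles were tested on simulated data with known ratios, made from the macrophage-like counts. Alternatives covered the cell filter, doublets, Leiden resolutions of 0.5 and 2.0, centring of components per library, the denominator of shares, TMM scaling (edgeR 4.0.16 in R 4.3.3), weighting of cells or clusters, thinning to 1000 UMIs per cell and the UMI minimum of list members, with further ones added later. Computation used Python 3.11.15, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9. The deposited counts were the only measurements used.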

Results

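Gene expression was measured as UMI counts in single CD45+ cells from B16F10 melanomas, with 1 WT and 1 KO library, each from 3 pooled mice. The WT library held 9677 barcodes and 55219440 UMIs, with a median of 3951 UMIs and 1555 genes per barcode. The KO library held 6356 barcodes and 57047535 UMIs, with a median of 6826.5 UMIs and 2111 genes. After filtering, 8936 WT cells (median 4398.5 UMIs) and 5686 KO cells (median 8013 UMIs) remained in 28 clusters. Mitochondrial content above 15% had removed 734 WT barcodes (7.59%) and 665 KO barcodes (10.5%). There were no replicate libraries, so each difference between WT and KO is one between these libraries, with intervals for counting error only.

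The labels give the purpose of the study as examining the impact of Kir2.1, the inwardly rectifying potassium channel that Kcnj2 encodes, on the tumour microenvironment. In the KO mice, Cre recombinase was expressed from the Lyz2 locus, which is active in macrophages, monocytes and neutrophils. In macrophage-like cells Kcnj2 was lower in the KO library, at 10.0 CPM (95% interval 7.98 to 12.4, 83 UMIs in 807 cells) against 24.9 CPM (20.4 to 30.2, 104 UMIs in 495 cells) in the WT library, a log2 ratio of -1.31 (-1.75 to -0.89). In monocyte-like cells it was 2.24 CPM (9 UMIs) against 8.02 CPM (17 UMIs), a log2 ratio of -1.84 (-3.19 to -0.60). Lyz2, the lysozyme gene of myeloid cells and the Cre driver locus, was also lower in the KO library. A Cre insertion at that locus can itself lower Lyz2 mRNA, so the lower level need not be a change of myeloid state. Lyz2 was at 1502 against 8039 CPM in macrophage-like cells (log2 ratio -2.42, -2.45 to -2.39), 7774 against 19440 CPM in monocyte-like cells (-1.32) and 138 against 696 CPM in type 2 conventional dendritic cell (cDC2)-like cells (-2.34). Lyz2 UMIs were found in 52.4% of KO and 97.2% of WT macrophage-like cells and in 67.3% and 100% of monocyte-like cells. They were also found in 6.14% of KO and 16.7% of WT CD8 T cell-like and 4.79% and 13.6% of B cell-like cells. The ratio was below 0 in these as well (-1.78 and -0.89), so free RNA is not excluded as a part of the Lyz2 values outside macrophage-like and monocyte-like cells.

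Kcnj2 (ENSMUSG00000041695) lies on chromosome 11 of GRCm38 from 111066164 to 111076821 on the plus strand. Its exon 1 (111066164 to 111066334) is untranslated, and exon 2 (111071549 to 111076821) holds the whole coding sequence (111071784 to 111073067) and the 3' UTR (111073068 to 111076821). Lyz2 (ENSMUSG00000069516) lies on chromosome 10 from 117277331 to 117282321 on the minus strand. The labels do not give which part of Kcnj2 was deleted, and 3' tags from an intact 3' UTR would check nothing of the deletion. Kcnj2 UMIs were found in 13.9% of WT (11.0 to 17.3) and 6.07% of KO (4.53 to 7.95) macrophage-like cells, at median depths of 8694 and 10131 UMIs. In CD8 T cell-like cells, which should lack the gene, 0 of 1434 WT cells (which allows up to 0.257%) and 1 of 293 KO cells (0.341%) held one, at median depths of 5423.5 and 5101 UMIs. With every cell thinned to 1000 UMIs, the shares were 1.66% (0.718 to 3.24) of WT and 1.01% (0.435 to 1.97) of KO macrophage-like cells and 0 in both libraries' CD8 T cell-like cells, so the difference in the share of cells was not detectable at that depth. In neutrophil-like cells Kcnj2 was at 13.2 CPM (1 UMI in 24 cells) in KO against 24.9 CPM (11 UMIs in 142 cells) in WT, a log2 ratio of -0.92 (-6.35 to 1.87) that leaves the direction open. In cDC2-like cells it was at 0.729 against 1.33 CPM (-0.87, -2.32 to 0.61). No Kcnj2 UMI was found in NK cell-like, B cell-like or melanoma-like cells of either library.

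Lyz1, the paralog next to Lyz2 (chromosome 10, 117287797 to 117292868), went the other way. It was at 250 CPM in KO and 27.6 CPM in WT macrophage-like cells (log2 ratio 3.18, 2.91 to 3.46) and at 466 against 20.8 CPM in monocyte-like cells (4.49). Lyz1 and Lyz2 are similar in sequence and reads can be assigned to the wrong one, so the Lyz1 values are uncertain. A fixed share of misassigned Lyz2 reads would have made Lyz1 lower in KO, as Lyz2 was, whereas Lyz1 was higher. This argues against such reads as the source of the difference. In macrophage-like cells 5 cells held 78.3% of the WT and 21.6% of the KO Lyz1 UMIs. In monocyte-like cells 5 cells held 95.5% of the 44 WT UMIs and 39.7% of the 1874 KO UMIs. In macrophage-like cells the Y-linked genes were near each other in the 2 libraries: Ddx3y was at 89.9 CPM in WT and 102 CPM in KO and Eif2s3y at 79.1 and 79.5 CPM. In melanoma-like cells both were lower in KO, Ddx3y at 2.21 against 12.2 CPM (-2.47, -3.70 to -1.41) and Eif2s3y at 1.23 against 8.97 CPM (-2.87). Xist, which female cells express, had 3 UMIs in WT and 1 UMI in KO macrophage-like cells.

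**Figure D1:**
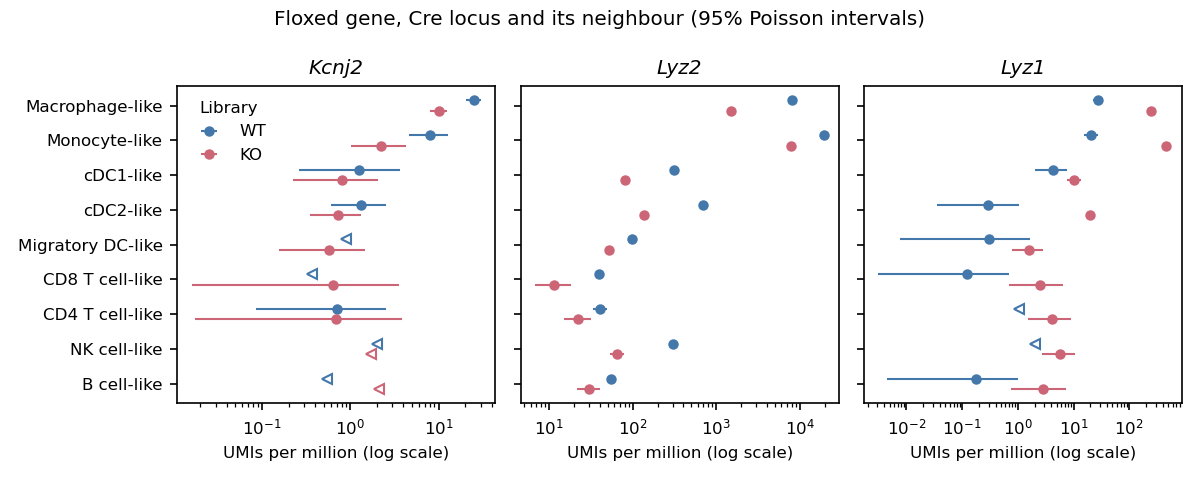
CPM (log axis) of Kcnj2, Lyz2 and Lyz1 in each cell class of the WT and KO libraries, with exact Poisson 95% intervals for counting error only; open triangles pointing left mark the level of 3 counts where a library had no UMI. In macrophage-like cells Kcnj2 was at 24.9 CPM in WT and 10.0 CPM in KO, and Lyz2 at 8039 and 1502 CPM.

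The first comparison asks which immune cells made up the tumour infiltrate. T cell-like cells made up 14.9% of the immune cells of the KO library (95% interval 14.0 to 15.8, 833 of 5598 cells) and 26.7% of those of the WT library (25.7 to 27.6, 2349 of 8813 cells), a log2 ratio of -0.84 (-0.94 to -0.74). CD8 T cell-like cells, the cytotoxic lineage, were at 5.23% against 16.3%, and B cell-like cells, the antibody-producing lineage, at 7.09% against 20.7% (log2 ratio -1.55, -1.70 to -1.40). Conventional dendritic cell-like cells, which present antigen to T cells, were at 35.3% in the KO library (34.0 to 36.6) against 13.6% in the WT library (12.9 to 14.4), a log2 ratio of 1.37 (1.28 to 1.46). Macrophage-like and monocyte-like cells together were at 22.0% (20.9 to 23.1) against 8.50% (7.92 to 9.10), a log2 ratio of 1.37 (1.25 to 1.49).

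Within the myeloid families the proportions of the classes were alike in both libraries. Macrophage-like cells were 5.62% of WT and 14.4% of KO immune cells, which was 66.1% (62.6 to 69.5) and 65.7% (62.9 to 68.3) of the mononuclear phagocyte-like cells. The cDC2-like cells were at 6.58% of WT and 17.5% of KO immune cells. Type 1 conventional dendritic cell (cDC1)-like cells were at 2.25% and 5.98%, and migratory dendritic cell-like cells, which express the lymph node homing receptor Ccr7, at 4.81% and 11.8%. Among conventional dendritic cell-like cells (cDC1-like, cDC2-like and migratory, without plasmacytoid cells), cDC2-like cells made up 48.2% of WT and 49.7% of KO. Plasmacytoid dendritic cell (pDC)-like cells, which can make large amounts of type I interferon, were at 2.41% (2.10 to 2.75) of WT and 2.54% (2.14 to 2.98) of KO immune cells, a difference within counting error. Neutrophil-like cells were at 1.61% of WT and 0.429% of KO (24 cells), and mast cell-like cells at 0.272% and 0.161%.

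The proportions of the lymphoid classes differed. Of the T and NK cell-like cells, CD8 T cell-like cells made up 53.0% (51.1 to 54.9) in the WT and 25.4% (22.9 to 28.0) in the KO library, and CD4 T cell-like cells 22.7% and 28.4%. Regulatory T cell-like cells, the Foxp3-expressing suppressor lineage, made up 3.55% (2.88 to 4.31) and 10.8% (9.02 to 12.7) of them, and NK cell-like cells 13.2% and 27.8% (25.2 to 30.5). Of all immune cells, NK cell-like cells were 4.06% in WT and 5.73% in KO, CD4 T cell-like cells 6.98% and 5.86%, and regulatory T cell-like cells 1.09% and 2.22%. Gamma-delta T cell-like cells were at 0.749% and 0.929%, and the remaining T cell-like cluster, led by Lef1 and Tcf7, 1.57% and 0.643%. Cells named T cell-like without a subset, here that last cluster, had a share ratio of -1.28, and of 3.69 with components centred per library. Centring clustered and named the cells anew, so the name may then have covered other cells than the Lef1-led cluster. The share ratio of NK cell-like cells was 0.27 instead of 0.50 with B cell-like cells left out of the denominator. Melanoma-like cells were 1.38% of kept WT cells and 1.55% of kept KO cells. No cluster was named for type 2 innate lymphoid cells, plasma cells, fibroblasts, endothelial cells, keratinocytes or erythroid cells. Shares sum to 100%, so a higher share of one class lowers the others, and the labels give no cell number per tumour.

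**Figure D2:**
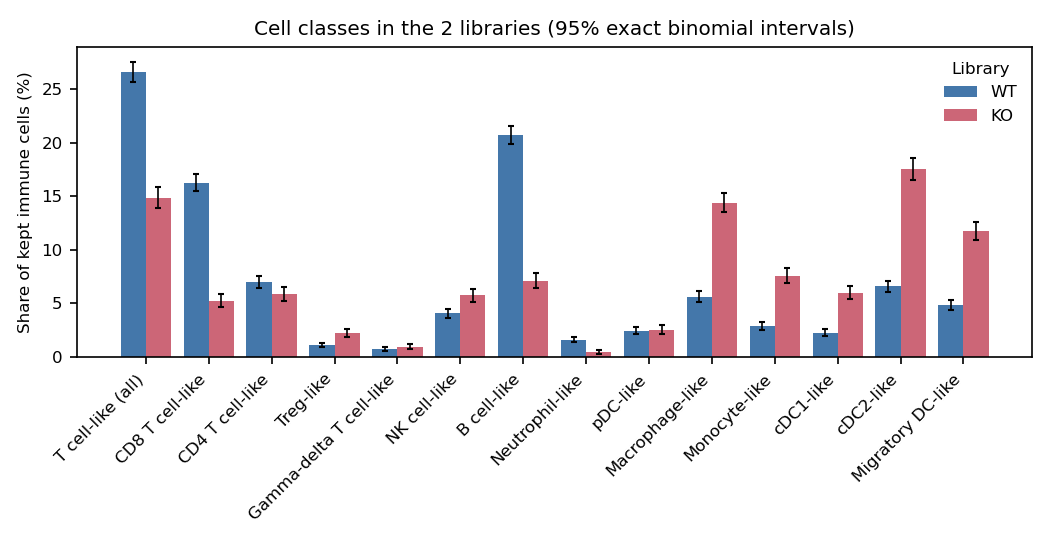
Share of immune cells (percent) of each cell class in the WT library (8813 cells) and the KO library (5598 cells), with exact binomial 95% intervals for counting error only. The cDC2-like and macrophage-like shares were higher in KO (17.5% and 14.4% against 6.58% and 5.62%) and the B cell-like and CD8 T cell-like shares lower (7.09% and 5.23% against 20.7% and 16.3%).

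In macrophage-like cells, genes of the antiviral type I interferon response were higher in the KO library. Of the 19 list members, 16 were higher and 0 lower, and the list median log2 ratio was 1.02 (counting interval 0.91 to 1.21), above all 10000 matched random lists. Oasl1, a relative of the oligoadenylate synthetases, was at 244 against 64.7 CPM (log2 ratio 1.91), and Rsad2, which encodes the antiviral enzyme viperin, at 878 against 236 CPM (1.89). Ifit1 was at 148 against 40.3 CPM (1.88) and Irf7, a transcription factor that amplifies interferon production, at 218 against 82.0 CPM (1.41). Ifnb1, the interferon-beta gene itself and outside the list, was at 139 against 52.7 CPM (1.40, 1.19 to 1.62). Immediate early genes were higher as well, 8 of 13 with 0 lower and a median of 0.60 (0.54 to 0.62), led by the transcription factor Egr1 at 1595 against 537 CPM (1.57).

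The remaining genes among the 12 highest were Lyz1, Lsmem1 (91.4 against 17.3 CPM, log2 ratio 2.40), Ifit3 (1.67), Slfn4 (1.58), Ifit2 (1.54) and Ifi206 (1.33), the last 4 being interferon-induced genes. The 12 lowest ratios belonged to Prg4, Saa3, Lyz2, Cd38, Serpinb2, Cxcl3, Cd37, Ms4a4b, Pf4, Spp1, Lpl and Hist1h1c. Spp1, which encodes osteopontin, was at 792 against 1694 CPM (-1.10), and the neutrophil-attracting chemokine gene Cxcl3 at 424 against 1018 CPM (-1.26). The lipoprotein lipase gene Lpl was at 146 against 301 CPM (-1.05) and the NAD-consuming enzyme gene Cd38 at 29.0 against 73.8 CPM (-1.35). Cxcl3 and Pf4 were also among the leading genes of the 2 macrophage-like clusters, so their ratios depend in part on which cells those clusters took in. Prg4, which encodes the lubricant lubricin, came from 12 WT cells and 1 KO cell (494 UMIs and 1 UMI, log2 ratio -9.94, -15.2 to -7.45), and Saa3, an acute-phase gene, from 43 WT and 14 KO cells (-5.15). The 12 Prg4-positive WT cells held 90.8% of the WT Saa3 UMIs, and in Prg4-negative cells Saa3 was at 40.1 CPM in WT and 11.96 CPM in KO, where 5 cells held 88.9% of its 99 UMIs. The 12 Prg4-positive cells also held 234 of the 551 WT UMIs of Serpinb2 (-1.27), so its place among the 12 lowest depends on them.

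**Figure D3:**
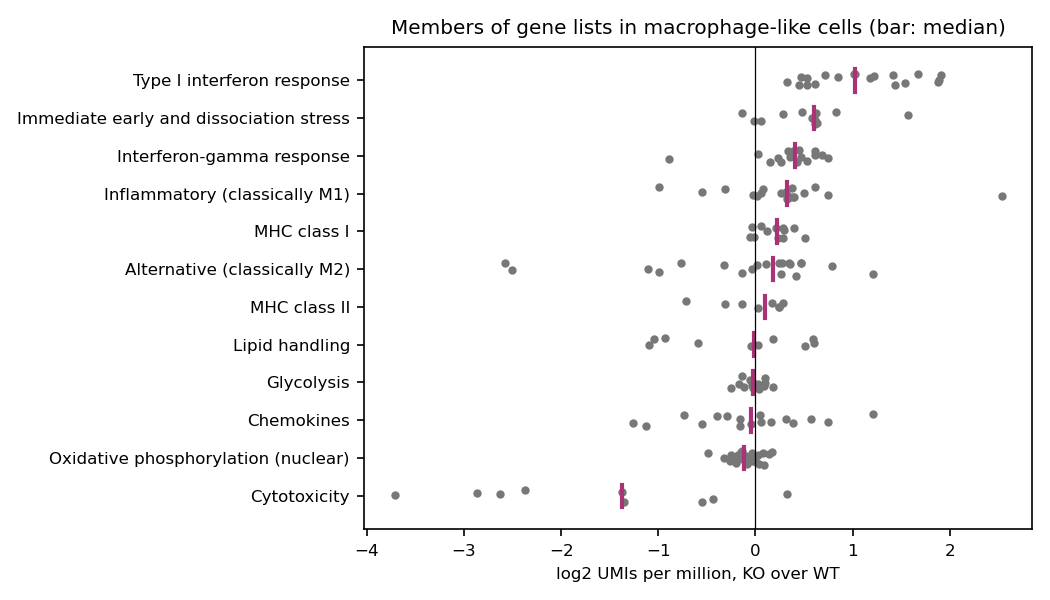
Log2 ratio of KO over WT CPM of the members of the plotted gene lists, a part of all lists, in macrophage-like cells. Each point is a gene with at least 20 UMIs and each bar the list median. The type I interferon list had the highest median (1.02) and the immediate early list stood at 0.60. The cytotoxicity list, made mostly of T and NK cell genes but also holding Tnf, had the lowest (-1.38).

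The inflammatory list, classically called M1, had 3 higher members and 1 lower of 19 in KO macrophage-like cells, with a median of 0.33 (0.23 to 0.37, percentile 99.96 of the random lists). The higher ones included Il12b, an interleukin-12 subunit (2.53, from 2 WT and 23 KO UMIs), and the T cell-attracting chemokine gene Cxcl10 (0.75), and the lower one was the chemokine gene Ccl5 (-0.55). Nos2 (0.02) and Il1b (0.07) were near 0. The alternative list, classically called M2, had 2 higher and 4 lower of 20 members, a median of 0.18 and a mean of -0.17, so the summary depended on the statistic. Ccl24 (1.21) and the transcription factor Klf4 (0.78) were higher. The arginase gene Arg1 (471 against 802 CPM, -0.77), Folr2 (-1.11), Lyve1 (-2.50) and Retnla (-2.58, from 21 WT and 7 KO UMIs) were lower. Folr2 was a leading gene of the smaller macrophage-like cluster (68 of 495 WT and 55 of 807 KO cells) and Arg1 of the larger one (427 and 752 cells), so their ratios depend in part on the make-up of the class.

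Among the other lists in macrophage-like cells, the interferon-gamma list, which shares Cxcl9 and Cxcl10, among others, with the inflammatory list, had 5 higher and 1 lower of 16 (median 0.41), and MHC class I 1 higher of 12 (0.22). MHC class II genes, which encode the antigen-presenting molecules for CD4 T cells, had 0 higher and 1 lower of 8, with a median of 0.10 and a mean of -0.03. Phagocytosis and lysosome genes had 2 higher of 13 (median 0.07), both receptors for dying cells, Mertk (1.10) and Axl (1.06). Lipid handling was split, with 3 higher and 4 lower of 10 (median -0.01). The cholesterol exporters Abcg1 (0.60) and Abca1 (0.51) and their regulator Nr1h3 (0.59) were higher. Lpl, Spp1, the fatty acid binding protein gene Fabp4 (-0.93) and the fatty acid receptor gene Cd36 (-0.59) were lower. Chemokines had 3 higher and 4 lower of 17 (-0.04).

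No glycolysis gene (15 members, median -0.03), oxidative phosphorylation gene (29, -0.11, percentile 1.34) or TCA cycle gene (13, -0.13) met the limit in macrophage-like cells. Glutamine and amino acid use had 1 lower of 13 (0.10), hypoxia 1 higher of 13, Vegfa at 0.54 (-0.14), and potassium channels 1 lower of 6, Kcnj2 itself (0.16). Proliferation had 2 lower of 15 (-0.21), mitochondrially encoded genes 1 higher of 10 (-0.03), sex-linked genes 0 of 4 (0.09) and neutrophil granule genes 1 higher and 1 lower of 3 (-0.41). The proliferation value leaves out the unnamed cluster led by cell cycle genes. T cell lists were lower or mixed: cytotoxicity 7 lower of 9 (-1.38), inhibitory receptors 1 higher and 2 lower of 6 (-0.15) and naive and memory genes 1 higher and 3 lower of 7 (0.06). Beside these, T cell markers in macrophage-like cells were lower in the KO library (log2 ratio -2.38, -2.58 to -2.19), as were B cell markers (-3.73, -4.04 to -3.43). Markers of migratory dendritic cells (0.48, 0.32 to 0.63), pDCs (0.42), monocytes (0.40) and type 2 innate lymphoid cells (0.40) were higher, in the same direction as the interferon list. KO migratory dendritic cell-like and monocyte-like cells held less of the interferon list (1023 and 2005 CPM) than WT macrophage-like cells (2088 CPM). RNA at these class levels would lower the list in macrophage-like cells rather than raise it. The pDC list shares Bst2 with the interferon list, so the pDC value is not independent of it. The alternative list median ran from -0.05 to 0.35 over 10 alternative settings and that of the inflammatory list from 0.20 to 0.43, and the MHC class II median from -0.07 to 0.26.

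In monocyte-like cells the type I interferon list had 13 higher and 0 lower of 19 members in the KO library (median 0.62, 0.57 to 0.90, above all random lists), among them Oasl2 at 124 against 47.7 CPM (1.38). Slfn5 (1.26) and Ifi213 (1.19), interferon-induced genes outside the list, the iron carrier gene Trf (transferrin, 1.38) and Fam71a (1.26) were also among the 6 highest, after Lyz1. MHC class II genes were lower, 3 of 8 with 0 higher and a median of -0.46 (-0.52 to -0.39), with the invariant chain gene Cd74 at -0.53. The chemokine genes Ccl5 (136 against 557 CPM, -2.03), Cxcl9 (-1.71) and Ccl7 (60.4 against 171 CPM, -1.51) were lower, as were the neutrophil calprotectin gene S100a8 (-4.01), Saa3 (-1.80) and Lyz2. The interferon-gamma list had 1 higher and 4 lower of 16 (-0.29), and hypoxia 0 higher and 2 lower of 11 (-0.30). T cell markers (-2.77, -3.07 to -2.47) and B cell markers (-2.01) were lower in the same cells, while those of migratory dendritic cells (1.01, 0.76 to 1.28), pDCs (0.52) and macrophages (0.37) were higher, in the direction of the interferon list. Of these, the pDC list shares Bst2 with the interferon list. Of the UMIs, 5 cells held 76.5% of WT and 80.5% of KO Cxcl9, and 60.5% and 76.1% of Ccl5, a T cell product too. For Saa3 5 cells held 73.2% and 84.5%, and for Ccl7 63.6% and 43.2%. S100a8 was found in 35 of 254 WT cells, with 65.1% of its WT UMIs in 5 cells. In KO it had 28 UMIs in 19 of 422 cells. Neutrophil-like cells were also at a lower share in KO (0.429% against 1.61%), while neutrophil markers were at -0.18 in monocyte-like cells. Whether S100a8 came from the monocyte-like cells themselves was not tested. Lyz1 and Lyz2 were among the leading genes of this cluster, and the interferon median was 1.12 without the 5 cells holding the most UMIs of each gene.

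In cDC2-like cells 12 of 19 type I interferon genes were higher and 0 lower in the KO library (median 0.74, 0.64 to 0.83), led by Oasl1 (1.49) and Rsad2 (1.28), and the viral RNA sensor gene Ifih1 was at 82.7 against 42.0 CPM (0.98). The interferon-gamma list had 10 higher and 0 lower of 16 (0.56, 0.49 to 0.62), with Socs1, a brake on cytokine signalling, at 1.05. The inflammatory list had 7 higher and 3 lower of 18 (0.42), with Il12b at 2.35 and the co-stimulatory receptor gene Cd40 at 0.63. Il1rn, which encodes the interleukin-1 receptor antagonist (1.14), and the immediate early genes Egr1 (1.10) and Nr4a3 (1.08) were higher, with Gdap10 (0.98). Chemokine genes were split, 7 higher and 6 lower of 17, with a median of 0.35 and a mean of -0.19. Cxcl1 (1.68) and Ccl24 (1.61) were higher, and Ccl2 (-1.17) and Ccl5 (-1.66) were lower. Lyz2 (-2.34), Spp1 (-1.82), Ms4a4b (-1.61) and the linker histone gene Hist1h1e (-1.07) completed the 6 lowest. For Spp1 5 cells held 72.7% of the WT and 48.3% of the KO UMIs, for Ccl2 54.8% and 22.2%, and for Rsad2 65.5% and 39.6%. T cell markers were at -3.15 (-3.34 to -2.96) and B cell markers at -3.17 in these cells, beside the lower Ccl5 and Ms4a4b, which T cells express. Those of cDC1 (0.50, 0.43 to 0.56), migratory dendritic cells (0.49, 0.42 to 0.57) and neutrophils (0.31) were higher, as the interferon and inflammatory lists were. Erythroid markers were far lower, at 0.365 CPM in KO against 554 CPM in WT (-10.57). With 96.2% of the haemoglobin UMIs of all kept WT cells in 5 cells, that WT level may rest on very few cDC2-like cells.

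In migratory dendritic cell-like cells the alternative list had 6 higher and 2 lower of 14 members (median 0.76, 0.47 to 0.82), with the mannose receptor gene Mrc1 at 2.67 and the chemokine gene Ccl17, which attracts Ccr4-bearing T cells, at 1.07. Areg, an epidermal growth factor receptor ligand gene, was at 167 against 44.9 CPM (1.90). Ptgs2, which encodes cyclooxygenase-2, was at 369 against 148 CPM (1.31) and Cxcl10 at 216 against 88.6 CPM (1.29). Cxcl2 (1.38), Tgfbi (1.26) and the lipid droplet gene Hilpda (1.21) were the other highest genes. Proliferation genes were lower, 6 of 13 with 0 higher (-0.61, -0.84 to -0.40), as were Ms4a4b (26.1 against 101 CPM, -1.95), the histone genes Hist1h2bc (-1.11) and Hist1h1e (-1.06), Fyb (-1.03), Lyz2 (-0.94) and the lymphotoxin-beta gene Ltb (-0.86). The unnamed cluster led by cell cycle genes (391 WT and 194 KO cells) belonged to no class, so the proliferation value leaves it out. The type I interferon list had 10 higher and 0 lower of 19 (0.65, 0.41 to 0.83), immediate early genes 7 higher and 0 lower of 13 (0.50) and chemokines 6 higher and 3 lower of 15 (0.36). T cell markers were at -1.61 and B cell markers at -2.59, while those of neutrophils (0.44), macrophages (0.30) and monocytes (0.29) were higher. The type 2 innate lymphoid cell list was at 1.14 (0.96 to 1.33), but Areg is one of its members. It held 149 of the 296 WT and 1170 of the 1380 KO UMIs of that list, so this value mostly repeats Areg. The interferon median was 0.15 with the Scrublet-marked cells kept and 0.33 with cells thinned to 1000 UMIs, and Cxcl2 was at -0.20 under the strict cell filter. Keeping the marked cells and the strict filter each clustered all cells anew, so the class may have held other cells. Lyz2 was at 0.13 with the marked cells kept, and 5 cells held 71.1% of WT and 55.8% of KO Areg UMIs, 78.2% and 60.9% of Cxcl10 and 52.4% and 39.4% of Cxcl2.

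In CD8 T cell-like cells, naive and memory genes were higher in the KO library, 4 of 8 with 0 lower (median 0.71, 0.40 to 0.81), among them the interleukin-7 receptor gene Il7r (1.07) and the transcription factor gene Klf2 (0.97). The survival gene Bcl2 was at 211 against 67.0 CPM (1.66) and the cytokine gene Tnf at 113 against 51.7 CPM (1.13), while Gzma, which encodes granzyme A, was at 389 against 814 CPM (-1.06). The cytotoxicity list as a whole had 1 higher and 1 lower of 10 (0.09). Of the inhibitory receptor list 2 were higher and 1 lower of 10 (0.38), with Tigit at 0.64 and Pdcd1, which encodes PD-1, at 0.58; its median was -0.18 without the 5 cells holding the most UMIs of each gene. The type I interferon list had 12 higher and 0 lower of 19 (0.75, 0.51 to 0.94), but without the CD8 T cell-like cluster that interferon genes led (87 WT and 32 KO cells) its median was 0.44 and that of the interferon-gamma list moved from 0.23 to -0.02.

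Ms4a4c (1.40), Fosb (1.27), Nfkbid (1.22) and Ifit3 (1.18) were the other highest genes in CD8 T cell-like cells. S100a4 (539 against 1147 CPM, -1.09), the inflammasome adaptor gene Pycard (-0.95), Wdr95 (-0.93), the receptor gene Cd160 (-0.89) and Ech1 (-0.83) were the other lowest. Immediate early genes had 6 higher and 0 lower of 13 (0.44) and oxidative phosphorylation genes 0 of 29 with a median of -0.26 (-0.31 to -0.20). Genes of antigen-presenting cells were higher too, MHC class II 5 and 1 lower of 8 (0.81) and the inflammatory list 6 of 12 (0.88), beside cDC2 markers at 0.89 (0.48 to 1.29) and B cell markers at -1.25.

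In CD4 T cell-like cells the type I interferon list had 9 higher and 0 lower of 16 members (0.62, 0.48 to 0.82), with Ifit3 at 2.17, and the immediate early list 6 higher and 0 lower of 13 (0.47), with Fosb at 318 against 105 CPM (1.60). Il7r (0.87) was among 3 higher of 8 naive and memory genes (0.38). Cytotoxicity genes were mixed, 4 lower and 1 higher of 10 (-0.24), with Tnf at 0.86, Gzmk at 0.38, Gzma at -1.77 and Ccl5 at 3560 against 6412 CPM (-0.85). Serpina3g (1.22), the activating receptor gene Klrk1 (1.19), Fosl2 (1.12), the folate receptor 4 gene Izumo1r (1.11) and the chemokine receptor gene Cxcr4 (1.09) were the other highest. Lztfl1 (-1.31), the collagen-binding integrin gene Itga1 (-1.21), S100a4 (-0.90), Arl6ip5 (-0.88), Kif2a (-0.87) and Ccl5 were the lowest. Oxidative phosphorylation genes had 2 lower of 29 (-0.23). With cells thinned to 1000 UMIs, Kif2a was at 0.28 and the interferon median at 0.40. The cytotoxicity median was 0.11 with only members of at least 100 UMIs, and B cell markers were at -1.40 in these cells. Erythroid markers were at 0 CPM in KO against 612 CPM in WT. Markers of cDC1 (0.81, 0.41 to 1.22) and migratory dendritic cells (0.51, 0.30 to 0.71) were higher there, in the same direction as the interferon list. The NK cell marker list was at 0.42, but Klrk1 held 151 of its 310 WT and 177 of its 213 KO UMIs. Its members Gzma (-1.77) and Prf1 (-1.26) were lower.

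**Figure D4:**
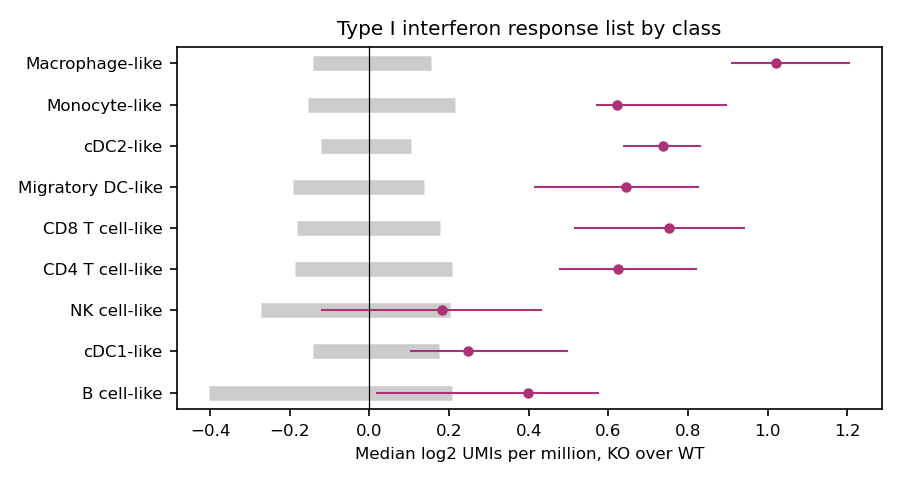
Median log2 ratio (KO over WT) of the type I interferon list in each cell class; whiskers are counting intervals and grey bars the central 95% of medians of matched random lists. The median was 1.02 in macrophage-like cells, between 0.62 and 0.75 in monocyte-like, cDC2-like, migratory dendritic, CD8 T and CD4 T cell-like cells, and 0.18 in NK cell-like cells.

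In NK cell-like cells, glycolysis genes were higher in the KO library, 7 of 14 with 0 lower (median 0.46, 0.35 to 0.59), with the enolase gene Eno1 at 0.84 and the triosephosphate isomerase gene Tpi1 at 0.71. Proliferation genes had 5 higher and 1 lower of 13 (0.46), again without the cluster led by cell cycle genes. The nucleotide synthesis genes Rrm2 (6 WT and 28 KO UMIs) and Tyms (11 and 39) were at 1.99 and 1.59. The lower member was Top2a (-0.68), and Mki67 was near 0 (-0.02). The granzyme genes Gzmc (408 against 92.0 CPM, 2.15) and Gzmb (1.06) were among 4 higher and 0 lower of 12 cytotoxicity genes (0.06). S1pr1, the receptor for exit from tissue, was lower (44.3 against 124 CPM, -1.48), with Cxcr6 (-1.57), Ly6a (-1.51), the CD8 chain gene Cd8b1 (-2.10), Lyz2 (-2.23) and S100a9 (-6.22). MHC class II genes had 4 lower of 8 (-0.57; 0.02 with cells weighted equally). Type I interferon genes had 3 higher of 17 (0.18, -0.12 to 0.43, percentile 95.58), a median within the random range that ran from -0.22 to 0.44 over the alternatives.

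Several of the NK cell-like ratios rested on a few cells: Mmp12 (6.39) on 2 WT and 3 KO cells, Ccl1 (6.20) on 3 and 7, and S100a9 on 9 and 3. For Gzmc, 5 cells held 88.2% of the WT and 74.5% of the KO UMIs, and for Lyz2 86.9% and 85.0%. In KO, 5 cells held 93.2% of the UMIs of Spp1 (2.84), 79.0% of Apoe (1.40), 73.3% of Atf3 (1.15) and 72.7% of Cd8b1. Markers of other cells moved alongside, with macrophage markers at 0.78, neutrophil markers at -2.77, T cell markers at -0.56 and B cell markers at -3.97. With the cells of the highest 6% of Scrublet scores removed, Mmp12 was at -0.24, Apoe at -0.45 and Atf3 at -0.59, and the lipid handling median moved from 0.82 to -0.32.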

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

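The result here was found by looking through data outside the comparisons, and no test of it was planned or run. An unnamed cluster of cells with few UMIs (median 1508 in WT and 1944 in KO), with Slfn4, an interferon-induced gene, as its first leading gene, made up 3.90% (3.42 to 4.44) of the kept cells of the KO library and 2.38% (2.08 to 2.72) of those of the WT library. It belonged to no named class, and its share stood above that of the WT library, which served as the control. Its median mitochondrial content was 9.90%, and macrophage was its top-scoring class. Macrophage-like cells were also at a higher share in KO, 14.4% against 5.62% of immune cells.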

How the results depend on the processing

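The alternatives chosen after seeing the data were those with at least 1000 UMIs and at most 5% mitochondrial UMIs, the highest 6% of Scrublet scores removed, unnamed clusters under their top-scoring class, B cell-like cells out of the denominator, clustering without Lyz1, Lyz2, Kcnj2, haemoglobin, interferon and immediate early genes, list medians from thinned cells, removal of the 5 cells with the most UMIs of each gene, and removal of the interferon-led CD8 T cell-like cluster. No paired analysis was possible because WT and KO each have 1 library and share fewer than 2 replicate numbers. Of the shares of all T, all conventional dendritic, mononuclear phagocyte, NK and B cell-like cells, 41 values stayed within the counting interval and 18 moved outside it, all with the same direction. Their log2 ratios ran from -1.10 to -0.77, 1.14 to 1.40, 1.10 to 1.40, 0.27 to 0.52 and -1.71 to -1.45. Kcnj2 in macrophage-like cells ran from -1.56 to -1.10. Of the list medians the comparisons rest on, 72 values stayed within and 25 moved. Among these the sign turned for the alternative list (thinned) and MHC class II (strict filter) in macrophage-like cells, and for interferon in NK cell-like cells without the 5 top cells and with members of at least 100 UMIs. It also turned, within the interval, for interferon in NK cell-like cells with the highest 6% of Scrublet scores removed and at 1000 UMIs and 5%. Of the other values, 114 shares, 1109 list medians and 620 named gene ratios stayed within, 27, 241 and 209 moved, and 1, 19 and 11 reversed, a term kept for shares whose interval left out 0, lists outside the random range and all named genes. Unless an alternative removes the cells or genes in question, the cause was not tested.

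All values below are log2 ratios of KO over WT, list values are medians, and interferon means the type I list. The strict filter, no filter, centring, keeping the Scrublet-marked cells and leaving out the listed genes each clustered and named the cells anew. Their classes may therefore hold other cells. At Leiden resolution 0.5 the shares of T, conventional dendritic and mononuclear phagocyte-like cells were -1.10, 1.26 and 1.11. For the dendritic and phagocyte shares, centred components gave 1.26 and 1.10, no cell filter 1.24 and 1.14, and the strict filter 1.16 and 1.14. For cells named T cell-like without a subset, centred components gave 3.69 against -1.28, perhaps in other cells than the Lef1-led cluster. At 1000 UMIs and 5% mitochondrial UMIs the T, dendritic and phagocyte shares were -1.03, 1.21 and 1.24. Without B cell-like cells in the denominator they were -1.07, 1.14 and 1.14, and the NK cell-like share 0.27. With unnamed clusters counted, the B and T cell-like shares were -1.71 and -0.99. Clustering without the listed genes moved 1 of 17 shares. Weighting clusters equally gave no value in monocyte, CD8 T, CD4 T and NK cell-like cells, which had fewer than 2 clusters with at least 50 cells in each library.

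Lyz2 in macrophage-like cells was -2.51 with the Scrublet-marked cells kept, -2.37 under TMM, -2.36 thinned, -2.38 with cells and -2.93 with clusters weighted equally, and -2.39 under the strict filter. In the same cells the inflammatory list was 0.38 under TMM, 0.20 thinned, 0.38 under the strict filter and 0.43 without the 5 top cells. The alternative list was 0.30 at 1000 UMIs and 5%, -0.049 thinned and 0.35 without the 5 top cells. MHC class II was 0.26 thinned, 0.21 and 0.22 with cells or clusters weighted equally and -0.069 under the strict filter. Interferon was 0.78 with clusters weighted equally and 1.24 without the 5 top cells.

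Without the 5 top cells, interferon was 1.12 in monocyte-like, 1.01 in cDC2-like, 0.96 in migratory dendritic and -0.20 in NK cell-like cells. In migratory dendritic cell-like cells it was also 0.15 with the marked cells kept, 0.33 thinned and 0.40 with clusters weighted equally. In CD8 T cell-like cells it was 0.43 with the marked cells kept and 0.44 without the interferon-led cluster. Thinned, it was 0.40 in CD4 T and 0.44 in NK cell-like cells, and with members of at least 100 UMIs -0.22 in NK cell-like cells.

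The values that reversed in that sense, beside the share of T cell-like cells without a subset above, were as follows. Keeping the 2 marked cells also meant clustering all cells anew, so its reversals need not come from those 2 cells. This setting gave Lyz2 0.13 and MHC class II -0.063 in migratory dendritic, interferon-gamma -0.059 in CD8 T, and Mmp12 -0.21, Apoe -0.0028 and lipid handling -0.0017 in NK cell-like cells. Thinning gave naive and memory 0.38 in monocyte-like, Kif2a 0.28 in CD4 T, and inflammatory -0.026, chemokines -0.0035 and TCA cycle -0.21 in NK cell-like cells. The 100 UMI minimum gave naive and memory 0.51 in monocyte-like and cytotoxicity 0.11 in CD4 T cell-like cells. MHC class II in NK cell-like cells was 0.020 with cells weighted equally, and proliferation in cDC2-like cells 0.046 with clusters weighted equally and 0.021 without the 5 top cells. The strict filter gave Cxcl2 -0.20 in migratory dendritic, and Mmp12 -0.80, Apoe -0.042, inflammatory -0.032, chemokines -0.14 and lipid handling -0.014 in NK cell-like cells. Removing the highest 6% of Scrublet scores gave Mmp12 -0.24, Apoe -0.45, Atf3 -0.59 and lipid handling -0.32 there. Removing the 5 top cells gave Apoe -0.47 and lipid handling -0.25 in NK, and inhibitory receptors -0.18 in CD8 T cell-like cells. Without the interferon-led cluster, interferon-gamma in CD8 T cell-like cells was -0.018.

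Depth limits the rarer classes: 969 kept WT cells (10.8%) and 203 KO cells (3.57%) had under 1000 UMIs, and with 24 KO cells the neutrophil-like class was left out of the gene and list comparisons, apart from the target gene values. In the simulated data, intervals held the true value for 95.3% of unchanged genes and for 92.0% to 98.0% of genes changed by a known ratio. Of unchanged lists, 5.0% fell outside the central range. Counts were drawn independently per gene and list members at random. UMIs held by few cells and list genes that vary together were not simulated. The values therefore check the computation and not the spread of real data.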

Other observations

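The tests of depth, dissociation stress, damaged cells, lymph node tissue, peritoneal B cells, free RNA, pDC RNA and both Prg4 explanations were chosen after the patterns themselves had been seen, and only for depth, dissociation stress and the first free RNA test were the bounds written before the value of the test was seen. B cell-like cells held more immediate early RNA in the KO library, 8 higher and 1 lower of 13 genes (median 0.57, 0.42 to 0.63), led by Fosb at 384 against 133 CPM (1.53). Their glycolysis genes were lower, 5 of 15 with 0 higher (-0.45, -0.58 to -0.30), with the triosephosphate isomerase gene Tpi1 at 111 against 206 CPM (-0.89), and so were hypoxia genes, 4 of 11 with 0 higher (-0.47). The 3 B cell-like clusters did not differ alike: the one led by Ighd, which naive B cells express, made up 10.3% of WT and 5.90% of KO immune cells, one with few UMIs 6.45% and 0.875%, and one led by Ighg2c and Jchain 3.98% and 0.322%, so the class values may mix different cells, and B cell-like interferon genes had 3 higher of 15 (0.40). Cytotoxicity genes, most of which belong to T and NK cells, were lower in them as well, 5 of 9 (-2.13), and the share ratio of the class was -1.71 with unnamed clusters counted.

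The cDC1-like cells, specialists in cross-presentation to CD8 T cells, fell just under the limit of 200 cells in the WT library (198 cells) and were left out of the main comparison. Their type I interferon genes had 5 higher and 0 lower of 17 (0.25, 0.10 to 0.50), with Oasl2 at 1.87. Chemokine genes had 5 higher and 2 lower of 13 (0.45), with the monocyte attractant gene Ccl2 at 1.73, and Ccl22, a ligand of Ccr4, was at 17.5 against 5.90 CPM (1.57). Proliferation genes had 0 higher and 2 lower of 14 (-0.29), with Rrm2 at -1.31, again without the cluster led by cell cycle genes.

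The lower share of T and B cell-like cells in the KO library could reflect damaged cells among those kept. Among cells with at least 1000 UMIs and at most 5% mitochondrial UMIs the T cell-like log2 ratio was -1.03 (-1.14 to -0.92). This argues against damage for T cell-like cells and cannot speak to cells lost before capture. The B cell-like class held a cluster of 568 WT and 49 KO cells with few UMIs (median 832.5 and 908) and 8.33% mitochondrial UMIs. The B cell-like ratio ran from -1.71 to -1.45 over 11 alternative settings. Lymph node tissue in the WT library would bring naive rather than effector cells, yet the Gzmk-led CD8 T cell-like cluster itself had a ratio of -1.71 (-1.90 to -1.53), which argues against it for that cluster. The measure first chosen, the naive minus the Gzmk-led ratio, was 0.43 (-0.13 to 0.99) and did not separate the explanations, and it was replaced after the cluster counts had been seen, so lymph node origin stays open for the B cell-like and naive T cells. Peritoneal B cells may have contributed, since the Jchain-led cluster had 9 of 9 B-1 cell genes above the other B cells. Without its 351 WT and 18 KO cells the B cell-like ratio was -1.31 (-1.46 to -1.15), with the cluster of few UMIs still counted. Genotype, handling, loss of lymphocytes before capture and differences between the pooled mice stay open, as 1 library per genotype confounds them.

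For the higher type I interferon list in the KO library, the macrophage-like median was 1.13 with cells thinned to 1000 UMIs and 0.911 over quartiles of immediate early gene level, which argues against depth and against dissociation stress as read by those genes. Free RNA was tested 4 times: the first test, list UMIs per antigen-presenting gene UMI in KO CD4 T cell-like cells over the highest myeloid or dendritic value, gave 3.25, above the bound of 2 set for it, but the WT value was 5.69, so RNA made by the T cells themselves passes it in either library and the bound was wrong. A test added next left free RNA in CD4 T cell-like cells open, since the KO minus WT difference of 291 CPM was 1.07 times the 272 CPM that free RNA could bring at most, and the explanations cannot be told apart there. KO macrophage-like cells held 0.961 times the list level of the highest other class (4133 against 4300 CPM in pDC-like cells), so pDC RNA could in principle be a source, which was followed up last: it would have to make up 92.5% of their RNA, while 5 pDC marker genes reached 1.32% of their pDC level (120 against 9129 CPM). A stronger interferon response of KO macrophage-like cells may thus be real in these cells, as a hypothesis, with genotype, handling and infection or housing of the mice untested.

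Prg4 in WT macrophage-like cells may mark peritoneal macrophages taken with the WT tumours, which a CD45 sort would not remove: of the 12 Prg4-positive cells, 11 (91.7%, 61.5 to 99.8) held a UMI of F5, Gata6, Garnl3, Cxcl13 or Vsig4, against 26 of 483 Prg4-negative cells (5.38%). In the 12 cells Alox15 had 96 UMIs, Cd5l 70, F5 57 and Gata6 9, but Cxcl13 had 0 and F5, the most frequent of the 5 genes, was also found in 80 KO macrophage-like cells, so F5 alone does not mark a peritoneal cell. A measure over 11 other genes of the 12-gene peritoneal list came first (at least 2 of them in 91.7% against 0.414%) and was replaced because 7 of the 12 had been seen before the list was written, and 2 of the 12 had at least 20 UMIs in Prg4-negative WT macrophage-like cells. Free RNA was argued against by Prg4 in WT T cell-like cells at 0.0204 times its level in WT macrophage-like cells. The same 12 cells held 90.8% of the Saa3 UMIs of WT macrophage-like cells. Among Prg4-negative cells Saa3 was still at 40.1 CPM in WT against 11.96 CPM in KO, from few cells. Prg4-negative WT cells also held UMIs of peritoneal list genes (the 12 cells held 39 of 65 Fcna and 35 of 50 Timd4 UMIs). KO macrophage-like cells held 14 Fcna and 5 Timd4 UMIs, so these genes need not mark peritoneal cells. How far peritoneal cells account for the Saa3 difference stays open, as does a biological difference in such macrophages between the genotypes.

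Haemoglobin UMIs were at 562 in WT and 1.20 in KO for each 1e6 UMIs of kept cells, with 96.2% of the WT UMIs in 5 cells. An unnamed cluster of cells with few UMIs made up 6.92% of kept WT and 0.879% of kept KO cells. Immunoglobulin UMIs in T cell-like cells were at 423 and 288 CPM. Melanoma marker UMIs outside the melanoma-like cluster were at 25.0 CPM in WT and 26.0 CPM in KO.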
